A study of Mus musculus with 6 samples.

How the data were processed

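RNA of sorted mammary gland macrophages was measured in 6 libraries, 3 at 8 weeks and 3 at 11 weeks. Libraries were made from under 100 ng of RNA with a low-input amplification kit and a transposase kit, per the labels' protocols. The submitters' processing notes name STAR 2.4, DESeq2 1.6 and the GRCm38 build, with no role given, and the counting tool and annotation release are not given in the sources used here. The deposited table lists 43432 genes with 1 signal value per library, which the values themselves show to be gene counts divided by 1 size factor per library and written to 1 decimal. The same deposited table carries the authors' own comparison of 11 with 8 weeks, as a log2 fold change, a linear fold ratio, a p-value and an adjusted p-value.

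Each library's values are whole multiples of 1 step, the worth of 1 read. Dividing by the step gave whole reads within 0.05 normalized counts for at least 99.696% of the nonzero values in each library. DESeq2 size factors computed from these reads equalled the deposited scaling. Table columns were matched to samples by the age and number in both names. No pair of libraries held identical values, and chi-square per degree of freedom between libraries of one age was 125.61 to 359.14, above counting noise, so no pair looked like 1 library deposited more than once. This does not tell repeat libraries of one sample from separate animals.

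For whole-number counts the planned main test was the edgeR quasi-likelihood test with TMM scaling. It was replaced, as planned for normalized values, by limma with trend and robust empirical Bayes on log2(normalized count + 1). Age was the only term. Genes with a mean of at least 1 normalized count in either age were tested, and p-values were adjusted by Benjamini and Hochberg at 0.05. Fold changes are differences of mean log2(value + 1). The added 1 understates the change of low genes, while a single library near 0 can overstate it. Gene lists written before the data were examined (47 lists, 958 entries, of which 941 matched by symbol, 7 through the gene ID and 7 not at all) were tested with camera at a preset correlation of 0.01 where at least 5 members were tested. An estimated correlation and fry were the alternatives. The shared replicate numbers were not taken as pairs, since different mice were taken at the 2 ages.

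Named genes follow a rule set before the data were examined: called genes with a mean of at least 8 normalized counts, a proper symbol and no overlap between the ages, up to 15 per direction; up to 4 members with the smallest p of each list; and all sort antigens. Genes named outside it are said to be so where they appear. Gene spans come from the deposited table. Of its genes 42462 were found in a GRCm38 annotation, and 99.88% of these overlapped the span given there. Strand is not stated to have been used in counting, so reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

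Alternatives covered the test (edgeR quasi-likelihood, DESeq2 and limma-voom on the recovered reads), the scaling, the filter, the pseudocount, a replicate block, a minimum 2-fold change and leaving out each library. The planned normalization alternatives and the planned fold threshold were run within limma, since the values were not counts.

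The steps were tested on simulated data with known answers, for the comparison of 11 with 8 weeks: 5 simulations of 24184 genes drawn from the real means, depths and dispersions, with 200 genes changed. limma found 14.2% of the 2-fold and 65% of the 4-fold changes, and 5.7% of its calls were unchanged genes. edgeR found 14% and 66.2%, with 4.8% unchanged genes among its calls. DESeq2 found 28.6% and 80.6%, and 51.2% of its calls were unchanged genes. With no gene changed, limma called 0 to 2 genes, edgeR 0 and DESeq2 62 to 74.

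The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.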

Results

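Macrophages were taken from the mammary glands of MMTV-PyMT mice on the FVB/N background, a strain in which a mammary tumour virus promoter drives the polyomavirus middle T oncogene and tumours form in the glands. Digested glands were stained and sorted by flow cytometry for live cells carrying CD45 (a marker of leukocytes), MHC class II (which presents antigen to helper T cells) and CD14 (a co-receptor for bacterial lipopolysaccharide). RNA from these cells was sequenced at 8 weeks and at 11 weeks, with 3 libraries at each age, and the series title places the comparison within tumour progression. The labels number the samples of each age but do not state that each came from its own animal, so p-values measure the spread between these samples, which may be technical. The recovered depth was 38784434 to 75004882 reads per library. Mitochondrial ribosomal RNA took 35.2% to 51.8% of the normalized counts, and 17385 to 19722 genes had at least 1 read.

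The libraries separated by age on the first principal component, which held 31.8% of the variance of the 1000 most variable genes. The 8-week libraries lay between -52.56 and -11.11 and the 11-week libraries between 23.8 and 47.09. The second component, with 22.8%, set 8-week replicate 2 (61.14) against 8-week replicate 3 (-60.53), so the 8-week libraries differed more among themselves than the 11-week libraries on that component. Pearson correlations across 10727 genes were 0.8753 to 0.9115 within 8 weeks, 0.8974 to 0.9021 within 11 weeks and 0.8585 to 0.9117 between ages. The highest of all, 0.9117, was that of 8-week replicate 1 with 11-week replicate 2. On component 1, too, 8-week replicate 1 (-11.11) lay nearer to 11-week replicate 2 (23.8) than to the other 8-week libraries. Genes are not independent replicates in these correlations.

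**Figure D1:**
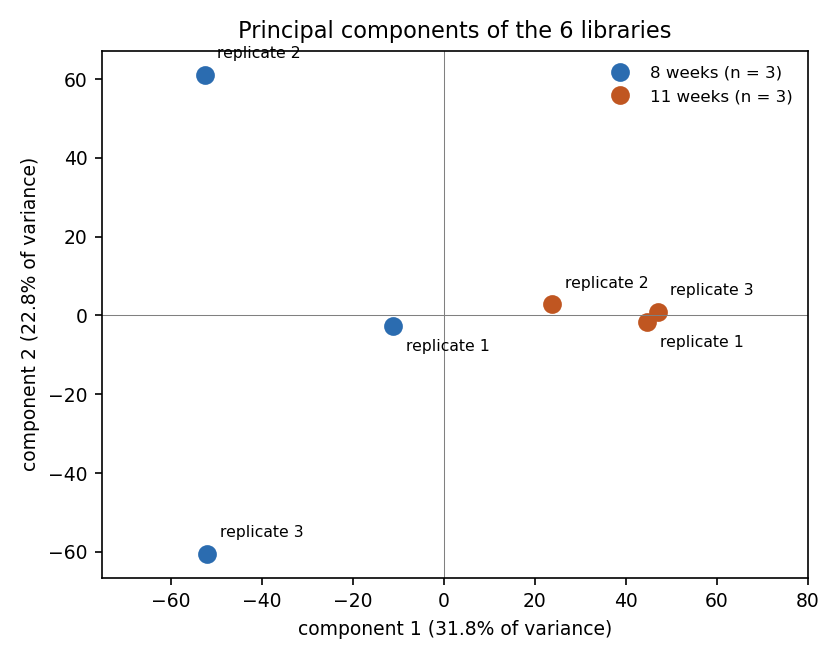
Scores of the 6 libraries on the first 2 principal components (arbitrary units) of the 1000 most variable genes, with 1 point per library. The 3 libraries of 8 weeks lie at negative scores of component 1 and the 3 libraries of 11 weeks at positive scores.

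At 11 weeks the sorted cells held more transcript of Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, of the monocyte-attracting chemokines Ccl7 and Ccl2, and of Emp1, Igfbp5, Lcn2, Nupr1 and the milk protein gene Csn3. Mammary epithelial transcripts, Csn3 among them, were higher as a list, with a median log2 fold change of 1.79 (camera adjusted p = 6.38e-13; adjusted p = 0.243 with an estimated correlation). The sorted cells held less of Cd74, the invariant chain that escorts MHC class II molecules, of the class II beta chain gene H2-Ab1, and of Fn1, which encodes fibronectin. Hmox1 stood at 22920 ± 7272 normalized counts at 8 weeks and 97513 ± 24318 at 11 weeks (SD, n = 3 per age), a log2 fold change of 2.10 ± 0.21 (SE; limma adjusted p = 0.000745). Ccl7 went from 8759 ± 559 to 28235 ± 7397 (SD, n = 3; limma adjusted p = 0.00138) and Ccl2 from 14695 ± 1034 to 34624 ± 7828 (SD, n = 3; limma adjusted p = 0.0127). Cd74, at 206800 ± 11778 normalized counts at 8 weeks, was at 104660 ± 9199 at 11 weeks (SD, n = 3), a log2 fold change of -0.98 ± 0.11 (SE; limma adjusted p = 0.00111).

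Among the other called genes, Igfbp5, an insulin-like growth factor binding protein, had the largest log2 fold change, 2.53 ± 0.34 (SE; limma adjusted p = 0.00647). The log2 fold changes of Lcn2 (lipocalin 2, which binds bacterial siderophores), Csn3, Nupr1 and Emp1 were 2.05, 1.98, 1.46 and 1.05, with limma adjusted p of 0.0188, 0.000888, 0.0396 and 0.0047. Those of Fn1 and H2-Ab1 were -0.91 and -0.84, with limma adjusted p of 0.0354 and 0.0127. In each of these 11 genes the 3 libraries of one age all lay on the same side of the 3 of the other age.

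The spans given in the deposited table are in GRCm38. Hmox1 (ENSMUSG00000005413) covers positions 75093591 to 75100596 of chromosome 8. Ccl7 (ENSMUSG00000035373) covers positions 82045712 to 82047525 of chromosome 11. Ccl2 (ENSMUSG00000035385) covers positions 82035571 to 82037453 of chromosome 11. Cd74 (ENSMUSG00000024610) covers positions 60803848 to 60812646 of chromosome 18. H2-Ab1 (ENSMUSG00000073421) covers positions 34263209 to 34269418 of chromosome 17. The others are Csn3 on chromosome 5 from 87925579 to 87932665, Emp1 on chromosome 6 from 135362931 to 135383173, Igfbp5 on chromosome 1 from 72857932 to 72874884, Lcn2 on chromosome 2 from 32384633 to 32388252, Fn1 on chromosome 1 from 71585520 to 71653200 and Nupr1 on chromosome 7 from 126623249 to 126630861. All 11 are annotated as protein-coding genes, and each value is 1 total per gene. Which parts of a gene were counted is not given in the sources used here.

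**Figure D2:**
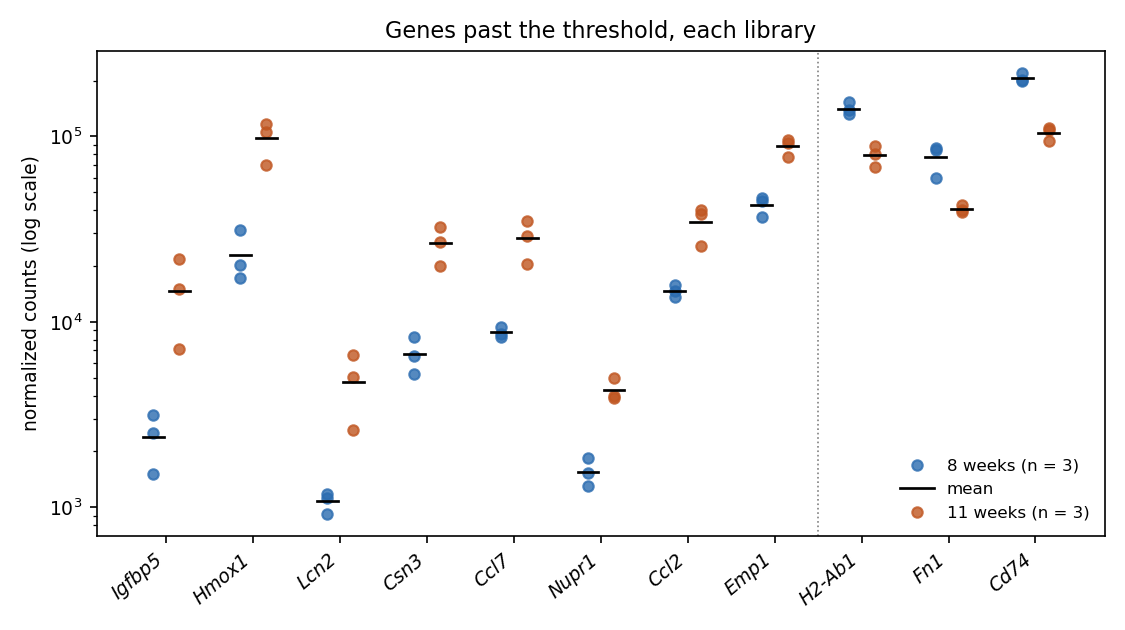
Normalized counts (log axis) of the 11 genes past the threshold, with 1 point per library and a bar at the mean of each age. Genes left of the dotted line were higher at 11 weeks and genes right of it lower, and Hmox1 rose from a mean of 22920 to 97513.

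Of 21675 genes tested with limma, 11 passed an adjusted p of 0.05, 8 of them higher and 3 lower at 11 weeks, and 1741 had an unadjusted p under 0.05. Values did not overlap between the ages in 11.92% of the tested genes, where chance gives 10%. With the libraries scaled to their totals in place of the deposited scaling, 4 genes passed and all were higher. The count rested on single libraries. It was 0 without 8-week replicate 1, 11-week replicate 1 or 11-week replicate 3, 1 without 8-week replicate 2 or 8-week replicate 3, and 8 without 11-week replicate 2. The edgeR quasi-likelihood test on the recovered reads called 3 genes (Hmox1, Csn3 and Ccl7), and DESeq2 on the same reads called 418. The authors' deposited table holds 272 genes with an adjusted p under 0.05, 161 higher and 111 lower, and it includes all 11.

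Genes of MHC class II presentation were lower at 11 weeks as a group. Of 16 tested members 14 had a negative log2 fold change, with a median of -0.855 (camera adjusted p = 4.67e-10; adjusted p = 0.173 with an estimated correlation). Cd74 and H2-Ab1 fell when adjusted over all genes, and 8 members fell when adjusted over the list alone. Ciita, the master transactivator of class II genes, was at 1933 ± 161 normalized counts at 8 weeks and 706 ± 251 at 11 weeks (SD, n = 3; limma adjusted p = 0.147 over all genes and 0.00107 adjusted over the list alone). H2-DMa and H2-DMb1, whose product loads peptide onto class II molecules, were at 12896 ± 2044 and 5415 ± 522 normalized counts at 8 weeks and 7050 ± 1037 and 2716 ± 372 at 11 weeks (SD, n = 3; limma adjusted p = 0.154 and 0.151 over all genes), of which H2-DMa was chosen after its values were seen. The class II chain genes H2-Aa and H2-Eb1 were lower on average, but their values overlapped between the ages. They were at 173890 ± 31114 and 1356 ± 332 normalized counts at 8 weeks and 120370 ± 39500 and 915 ± 262 at 11 weeks (SD, n = 3, limma adjusted p = 0.442 and 0.704 over all genes). Class II protein was itself part of the sort. Of the other sort antigens, Cd14 was at 21806 ± 2033 and 33730 ± 3977 normalized counts (SD, n = 3; limma adjusted p = 0.198) and Ptprc, which encodes CD45, at 34894 ± 1981 and 26153 ± 2707 (SD, n = 3; limma adjusted p = 0.434). MHC class I presentation genes had a median log2 fold change of 0.19 and macrophage core genes one of 0.034, with camera adjusted p of 0.327 and 0.647. The class I list passed without 8-week replicate 2 (camera adjusted p = 0.0369).

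**Figure D3:**
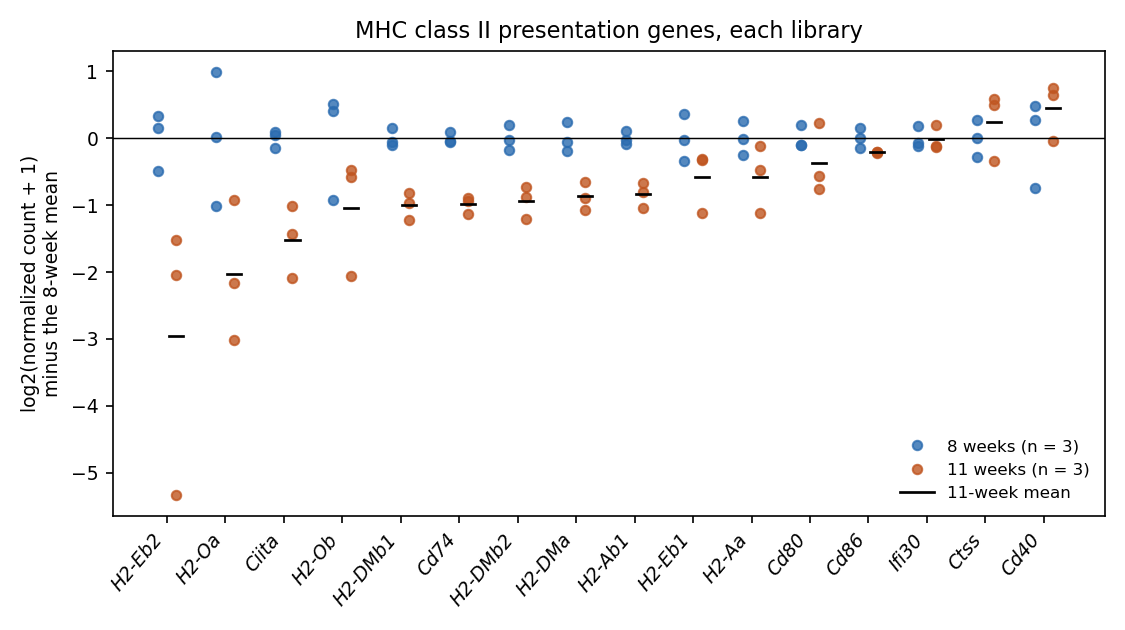
Log2(normalized count + 1) of the 16 MHC class II presentation genes minus the 8-week mean of each gene, with 1 point per library and a bar at the 11-week mean. The bar lies below 0 for 14 of the 16 genes.

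Chemokine genes were higher at 11 weeks, with 21 of 25 members positive and a median log2 fold change of 0.85 (camera adjusted p = 1.33e-09; adjusted p = 0.173 with an estimated correlation). Adjusted over the list alone, 9 members rose and 1 fell. Beside Ccl2 and Ccl7, Pf4 was at 11229 ± 1818 and 19582 ± 2888 normalized counts and Ccl8 at 10008 ± 1277 and 22862 ± 9426 (SD, n = 3; limma adjusted p = 0.157 over all genes for each). Inflammatory cytokines and NF-kB targets were higher as a list, with 18 of 22 members positive and a median of 0.65 (camera adjusted p = 6.6e-06; adjusted p = 0.319 with an estimated correlation), and 6 members rose when adjusted over the list alone. Il1b, which encodes interleukin 1 beta, was at 19964 ± 6907 and 40998 ± 6627 normalized counts and Il1rn, its receptor antagonist, at 21413 ± 5797 and 42729 ± 6095 (SD, n = 3; limma adjusted p = 0.132 and 0.0857 over all genes). Neutrophil markers moved with these lists: S100a9 was at 95.3 ± 80.4 and 1255 ± 242 normalized counts (SD, n = 3; limma adjusted p = 0.175 over all genes). The neutrophil list had a median of 1.62 (camera adjusted p = 2.59e-06, adjusted p = 0.173 with an estimated correlation). It shares Lcn2 with the called genes, which does not place Lcn2 in neutrophils. Among the 11-week libraries Lcn2 was lowest in replicate 2 (2597.8 normalized counts), as were Csn3 (19883.5), Ccl2 (25637.6) and Ccl7 (20456.1). S100a9 was highest there (1522.2).

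**Figure D4:**
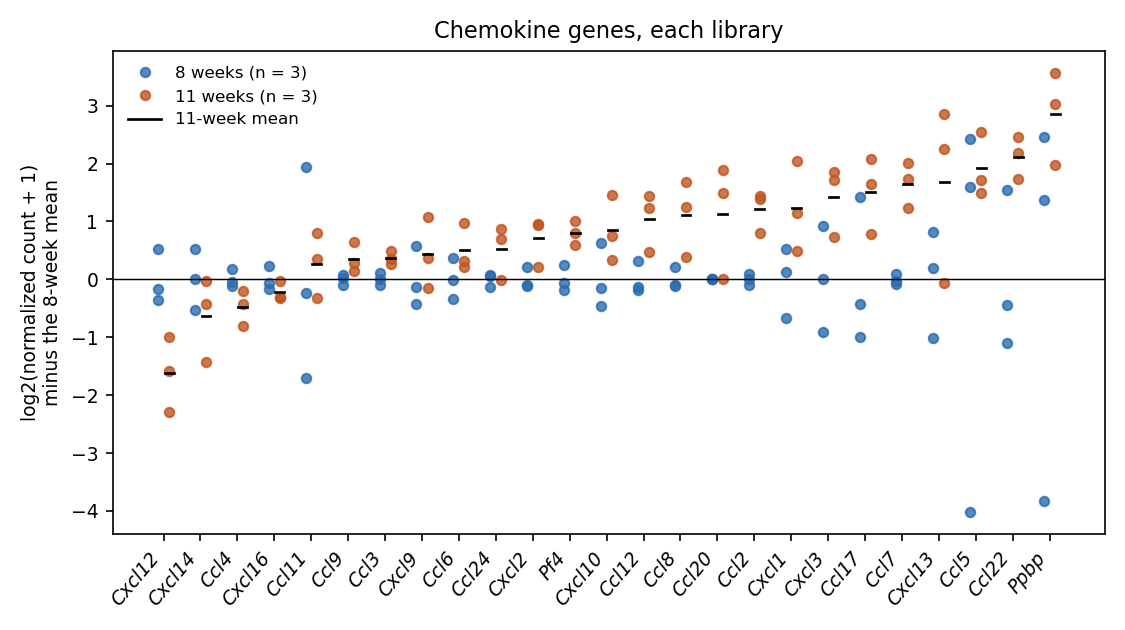
Log2(normalized count + 1) of the 25 chemokine genes minus the 8-week mean of each gene, with 1 point per library and a bar at the 11-week mean. The bar lies above 0 for 21 of the 25 genes.

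Genes of tissue-resident macrophages were higher at 11 weeks, with 22 of 27 members positive and a median log2 fold change of 0.44 (camera adjusted p = 2.72e-07; adjusted p = 0.374 with an estimated correlation), and 9 members rose when adjusted over the list alone. Lyve1, a hyaluronan receptor, was at 19579 ± 8262 and 37444 ± 9532 normalized counts (SD, n = 3; limma adjusted p = 0.2 over all genes). The endothelin receptor gene Ednrb was at 10659 ± 2177 and 19717 ± 2810 (SD, n = 3; limma adjusted p = 0.135 over all genes). Alternative activation genes had a median of 0.46 (camera adjusted p = 0.000444; adjusted p = 0.26 with an estimated correlation; camera adjusted p = 0.0847 without 11-week replicate 1), and 5 of 20 rose when adjusted over the list alone. Among them Il10 was at 5707 ± 2522 and 12883 ± 826 normalized counts and Arg1, which encodes arginase 1, at 1223 ± 450 and 3462 ± 1449 (SD, n = 3; limma adjusted p = 0.135 and 0.166 over all genes). Monocyte genes went both ways and the list did not pass (camera adjusted p = 0.647, with a positive median of 0.37 and a negative direction by camera), except by fry's mixed test (0.0212). Of its 16 members 10 were positive, and 1 rose and 3 fell when adjusted over the list alone. Fn1 fell, Itga4 was at 4296 ± 704 and 2068 ± 200 normalized counts, Ccr2, the receptor of Ccl2, at 17679 ± 6209 and 10333 ± 1594, and Vcan, which encodes the proteoglycan versican, at 533 ± 130 and 1442 ± 729 (SD, n = 3; limma adjusted p = 0.155, 0.415 and 0.35 over all genes). Lipid-associated tumour macrophage genes did not pass as a list (camera adjusted p = 0.0825). They passed with upper-quartile scaling (0.0411), with a mean of at least 100 normalized counts (0.0354), without 8-week replicate 2 (0.00215) and by fry's mixed test, which has no direction (0.0217).

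Transcripts of mammary epithelium and tumour cells were higher at 11 weeks, with 24 of 27 members positive and a median log2 fold change of 1.79 (camera adjusted p = 6.38e-13; adjusted p = 0.243 with an estimated correlation). Csn3 rose when adjusted over all genes and 12 members rose when adjusted over the list alone. Values of 8 of the 27 did not overlap between the ages. Epcam and Krt18, outside the rule for named genes and chosen after their values were seen, lay within their 8-week ranges in 11-week replicate 2. There they were at 276.2 and 251 normalized counts, against 656.5 and 860.6 in replicate 1 and 1370.4 and 1413.9 in replicate 3. Csn3, Csn2 and Wfdc18 lay above their 8-week ranges in all 3. The split did not follow milk protein genes. Krt19 and the prolactin receptor gene Prlr also lay above their 8-week ranges in all 3. The casein gene Csn1s2a, at 303.4 in replicate 2, lay within its 8-week range of 53 to 407.3. Krt19 and Csn1s2a, too, are outside the rule and were chosen after their values were seen. Csn2, which encodes beta-casein, was at 1625 ± 318 and 5569 ± 3523 normalized counts and Wfdc18 at 1237 ± 363 and 5432 ± 3879 (SD, n = 3, limma adjusted p = 0.157 and 0.135 over all genes). Matrix and matricellular protein genes had a median of 1.12 (camera adjusted p = 1.24e-07; adjusted p = 0.173 with an estimated correlation), although Fn1, their only member called over all genes, fell. Sparc was at 858 ± 373 and 2493 ± 1305 normalized counts (SD, n = 3; limma adjusted p = 0.255 over all genes). Fibroblast genes had a median of 1.32 (camera adjusted p = 0.000488; adjusted p = 0.251 with an estimated correlation), at low levels such as 202 ± 66.7 and 614 ± 253 normalized counts of Col1a1 (SD, n = 3; limma adjusted p = 0.399 over all genes). The lists of T cells, NK cells, B cells, endothelium, plasma cells and the 2 groups of conventional dendritic cells did not pass, with camera adjusted p of 0.325, 0.561, 0.347, 0.555, 0.112, 0.347 and 0.579. Plasmacytoid dendritic cell genes did not pass either (camera adjusted p = 0.231), with 6 of 9 members negative and a median of -0.474. The B cell list passed as lower with a mean of at least 100 normalized counts (camera adjusted p = 0.00657) and without 11-week replicate 3 (0.0361), and the T cell list by fry's mixed test (0.0275).

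Type I interferon response genes were higher at 11 weeks, with 28 of 30 members positive and a median log2 fold change of 0.73 (camera adjusted p = 8.52e-08; adjusted p = 0.408 with an estimated correlation). Without 11-week replicate 1 the list did not pass (camera adjusted p = 0.0847). Of them 1 rose when adjusted over the list alone, Oasl1, at 605 ± 246 and 2134 ± 743 normalized counts (SD, n = 3; limma adjusted p = 0.127 over all genes). Interferon gamma response genes did not pass (median -0.115, camera adjusted p = 0.367). Glycolysis and hypoxia response genes had medians of 0.30 and 0.21 (camera adjusted p = 0.0126 and 0.0235; adjusted p = 0.434 and 0.509 with an estimated correlation). Leaving out 8-week replicate 1, 11-week replicate 1 or 11-week replicate 2 ended the glycolysis call (camera adjusted p = 0.298, 0.0535 and 0.102) and the hypoxia call (0.237, 0.158 and 0.556), and leaving out 8-week replicate 3 also ended the hypoxia call (0.231). Scaling to library totals ended both calls (camera adjusted p = 0.0784 for each). Vegfa, a hypoxia-responsive angiogenic factor, was at 1679 ± 633 and 3276 ± 553 normalized counts (SD, n = 3; limma adjusted p = 0.31 over all genes). Heat shock genes were lower, with a median of -0.43 (camera adjusted p = 0.000106; adjusted p = 0.319 with an estimated correlation), and so were cell cycle genes, with 27 of 34 members negative and a median of -0.33 (camera adjusted p = 0.00094; adjusted p = 0.449 with an estimated correlation; camera adjusted p = 0.0664 without 11-week replicate 1). The cell cycle fall was uneven: in 11-week replicate 2 Mki67 and Top2a were at 20812 and 6881 normalized counts. Their 8-week ranges were 15300 to 23447 and 4136 to 6178. Both are outside the rule for named genes and were chosen after their values were seen. Rrm1, Bub1b and Mcm2 lay below their 8-week ranges in that library. Hspa1b and Hspa1a, near-identical copies whose reads cannot be assigned with certainty, had log2 fold changes of -1.19 and -0.91 (limma adjusted p = 0.31 and 0.479 over all genes). Immediate-early genes, which respond to tissue digestion, had a median of -0.018 (camera adjusted p = 0.484).

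**Figure D5:**
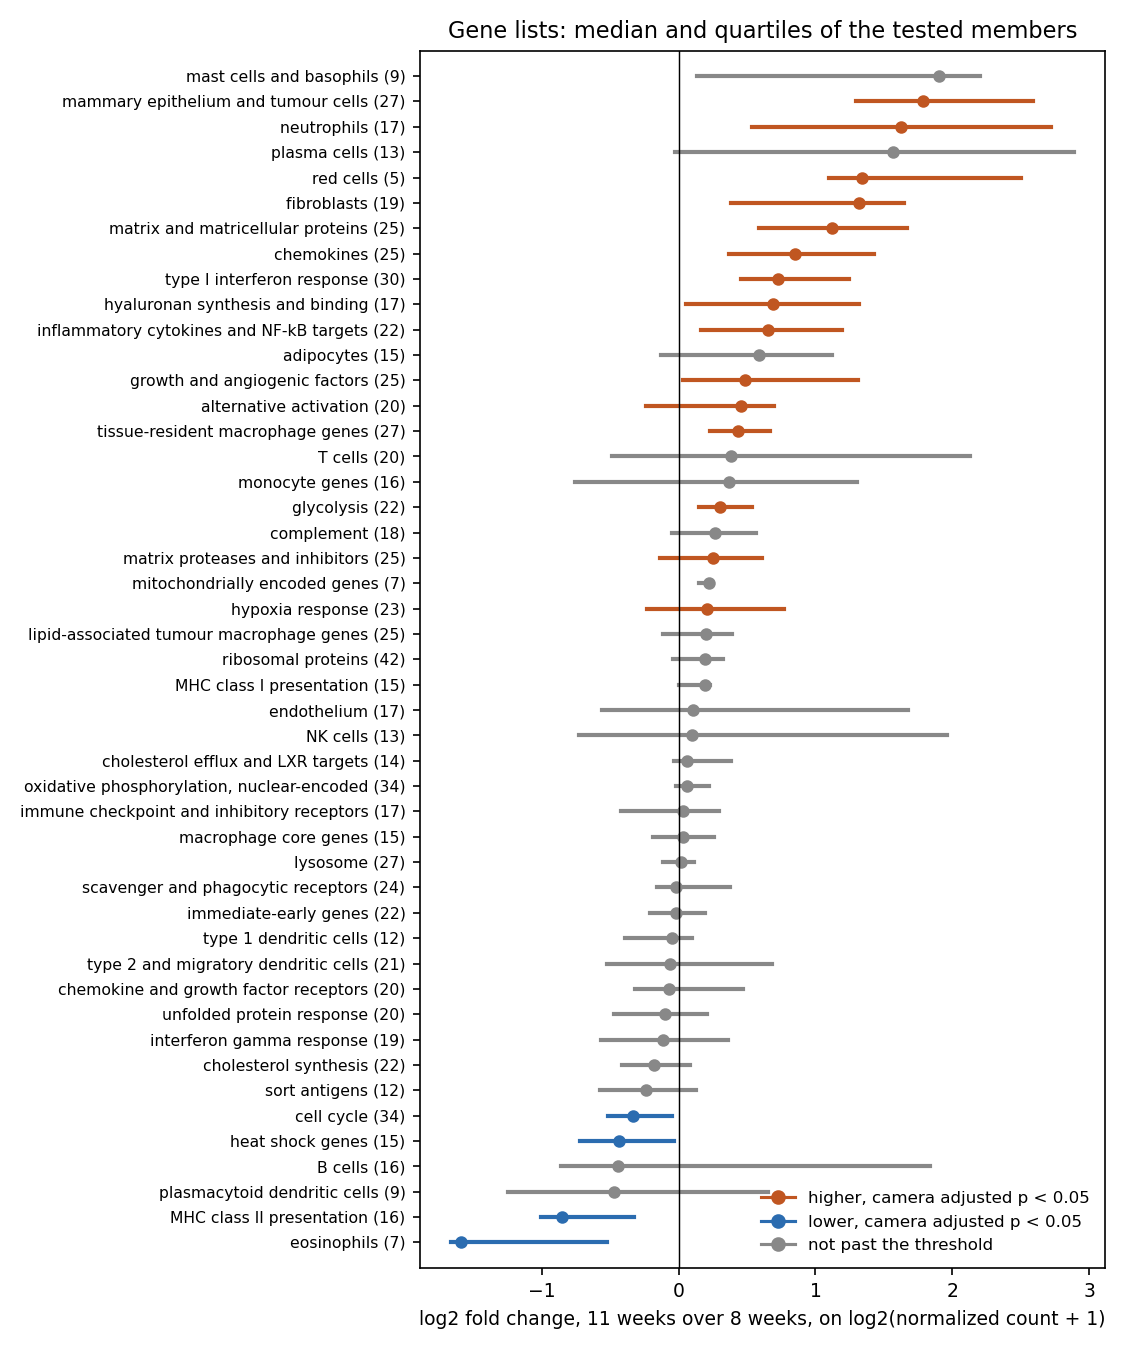
Median (point) and quartiles (line) of the log2 fold change of the tested members of each of the 47 gene lists, 11 weeks over 8 weeks, with the number of members in parentheses. By camera with a preset correlation 15 lists were higher and 4 lower, and none of them passed with an estimated correlation.

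In total 15 lists were higher and 4 lower of 47 tested by camera with a preset correlation of 0.01. The lists overlap and are not independent findings: their 915 tested entries held 800 distinct genes. Pf4 and Ccl8, for example, stand in the chemokine list and in that of tissue-resident macrophages. None passed with an estimated correlation, nor by fry's directional test, which asks whether the genes of a list move one way on balance. Of the called lists not described above, growth and angiogenic factors, red cell genes, hyaluronan genes and matrix proteases with their inhibitors were higher (camera adjusted p = 0.00322, 0.0038, 0.0161 and 0.0283) and eosinophil genes lower (0.015), with adjusted p of 0.198, 0.319, 0.374, 0.319 and 0.408 with an estimated correlation. The protease call ended with scaling to library totals (0.134) and without 8-week replicate 1, 8-week replicate 3, 11-week replicate 1 or 11-week replicate 2 (0.121, 0.257, 0.123 and 0.443). The hyaluronan call ended without 8-week replicate 1, 8-week replicate 2, 11-week replicate 1 or 11-week replicate 3 (0.145, 0.0847, 0.0703 and 0.139). The eosinophil call ended without 8-week replicate 2, 11-week replicate 2 or 11-week replicate 3 (0.0662, 0.0563 and 0.0742).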

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

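TMM scaling in limma, the mean of at least 100 normalized counts and the removal of mitochondrial rRNA were chosen after seeing the data. So were the camera fits under other scalings, that filter and a pseudocount of 0.1. The edgeR fit with TMM was the main test planned for whole-number counts. Its use on the recovered reads, as an alternative, was chosen after seeing the data. The 11 genes called by limma (8 higher, 3 lower) kept their direction under every alternative. Without 1 library this had to hold, since none of the 11 overlapped between the ages. TMM scaling and the removal of mitochondrial rRNA kept all 11 calls. edgeR called 3 genes on the recovered reads, 3 higher and 0 lower, with TMM and with RLE factors. At an unadjusted p under 0.05 it had 1272 and 1266. DESeq2 called 418 (265 higher, 153 lower), among them all 11, and limma-voom 26 (20 higher, 6 lower). Scaling to library totals gave 4 calls, 4 higher and 0 lower. The fit without robust estimation called 1 lower gene. A required 2-fold change left 0 genes, 0 higher and 0 lower, by limma's treat, with 425 at an unadjusted p under 0.05. In simulated data 51.2% of the calls of DESeq2 were unchanged genes, so its larger count carries more false calls there. The cause of the other differences was not tested. The deposited scaling is already that of DESeq2, so no separate camera fit with RLE factors was run.

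Without 1 library, calls were 0 to 8 in total, 0 to 7 higher and 0 to 1 lower, with fewer samples in each fit. Fits that left out 1 library also turned the direction of genes that had not passed, or took Lep and Il5ra, each read in 1 library alone, to 0. The lowest and highest log2 fold changes were -0.4877 and 0.0213 for Pdia3, -0.07 and 0.9783 for Srebf1, -0.0921 and 0.5959 for mt-Nd6, -0.0665 and 0.5063 for mt-Co1, -0.0904 and 0.5544 for mt-Nd2, 0 and 2.832 for Lep, -2.52 and 0 for Il5ra, -1.5223 and 0.0602 for Runx2, -0.2936 and 0.0599 for Itgax, -0.2857 and 0.7712 for Cd24a, -0.0252 and 0.1947 for Itgb1, and -0.3303 and 0.8335 for Pecam1. Scaling to library totals turned Itgb1 to -0.0174.

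Of the 15 higher and 4 lower gene lists, 0 and 0 passed with an estimated correlation and 0 and 0 by fry's directional test. By fry's mixed test, which has no direction, 17 lists passed, 14 of them among the 19. Lists that did not pass, and passed in some fits, include complement (0.0437 with upper-quartile scaling, 0.0368 without 8-week replicate 3, 0.0361 without 11-week replicate 3), ribosomal proteins (0.0411 with a mean of at least 100 normalized counts, 0.00161 without 11-week replicate 1), mitochondrially encoded genes (0.00494) and mast cells and basophils (0.0368) without 8-week replicate 3, and cholesterol efflux genes (0.044) without 11-week replicate 3.

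With the replicate number as a block (replicate block) limma called 45 genes, 37 higher and 8 lower, including 10 of the 11. Deviations of same-numbered libraries correlated at -0.046, -0.018 and -0.032 across 10127 genes, so no shared deviation showed across these genes together. An effect shared by same-numbered libraries on a smaller set of genes was not tested.

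Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many limma calls (11, the highest other 0), DESeq2 calls (418, the highest other 85) and gene lists (19, the highest other 15). With 10 splits the share cannot fall under 0.05. Depth was 38784434 to 75004882 reads, and in simulated data limma found 14.2% of the 2-fold changes, so smaller changes mostly went uncalled at this number of libraries.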

Other observations

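The tests of epithelial, dendritic cell, B cell, neutrophil, scaling, detection and digestion explanations were chosen only after the results they address were seen, while those of NRF2 target and of heme and iron genes were set before the medians they measure were seen. The changes of Txn1 and Slc40a1 had been seen by then, and Cd163 and Lrp1 belong to lists already tested. Txn1, Slc40a1, Gclc, Srxn1, Txnrd1, Dpp4, Cd79b and Ms4a1, and the genes of the next paragraph other than Ighm, are outside the rule for named genes and were chosen after their values were seen.

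Several genes differed between the ages by unadjusted p without passing limma's threshold. Emr4, an adhesion receptor of myeloid cells, was at 1016 ± 269 normalized counts at 8 weeks and 246 ± 30.9 at 11 weeks (SD, n = 3; limma adjusted p = 0.104), and Klrb1a at 369 ± 115 and 38.5 ± 32.6 (SD, n = 3; limma adjusted p = 0.156). Rgs5, a pericyte gene, was at 182 ± 55.2 and 971 ± 465, and Sox10, a neural crest gene, at 26.0 ± 30.4 and 410 ± 277 (SD, n = 3; limma adjusted p = 0.132 and 0.157). Ighm, the immunoglobulin mu heavy chain gene, was at 12734 ± 1455 and 8400 ± 1104 normalized counts, while Cd79a, needed for its surface display on B cells, was at 0.60 ± 1.04 and 14.5 ± 22.0 (SD, n = 3; limma adjusted p = 0.334 and 0.781).

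Mammary epithelial transcripts were higher at 11 weeks in cells gated on CD45, which epithelial cells lack. Fewer detected genes at 8 weeks are argued against as the whole cause: the median of the list was above every one of 10000 random lists matched on mean expression (percentile 100), whose 95th percentile was 0.292. Epithelial cells or their RNA among the sorted cells stay open. The members other than the casein genes, Wap and Wfdc18 had a median log2 fold change of 1.766. This decides nothing, since with 24 of 27 members positive it had to lie above 0. Uptake of tumour cell material by macrophages and age itself stay open too, and were not tested.

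MHC class II genes were lower, and a lower share of macrophage RNA or a wrong scaling is argued against by the macrophage core genes, whose median was 0.034 (quartiles -0.186 and 0.256) against -0.985 for Cd74. B cells are argued against by Cd79a, Cd79b and Ms4a1, whose sum at 8 weeks was at most 0.00283 of the fall of Cd74. That ratio replaced an earlier version over 16 B cell genes, whose median of -0.446 had a bootstrap 95% interval of -0.861 to 1.774. Fewer dendritic cells stay open, and the reading depended on the version of the test. Over all 21 genes that only the lists of type 1 and of type 2 and migratory dendritic cells hold, the median was -0.182. Its interval of -0.522 to 0.142 did not reach the change of Cd74. Over the 15 with a mean under 1000 normalized counts, the median was -0.065, with an interval of -1.118 to 1.058 that did. That limit was set after the first version was seen, because macrophages express many of the others. The bootstrap intervals here resample genes with the libraries fixed. They show spread over genes and are not tests across samples. Of the 15, 4 fell at least as far as Cd74 (Batf3, Fscn1, Dpp4 and Kmo), where matched random lists had 5 at their 95th percentile, and the list of plasmacytoid dendritic cells, which that test left out, had a median of -0.474, at percentile 4.27 of matched random lists.

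Inflammatory cytokine genes were higher. Neutrophils among the sorted cells stay open as a source of the rise of Il1b. The test used S100a8 and S100a9, abundant in neutrophils. Their joint rise of 1534 normalized counts was 0.0729 of the rise of Il1b (0.0418 to 0.151 over pairs of libraries), although neutrophil markers were higher too. The ratio assumes that neutrophils yield at least as many reads of S100a8 and S100a9 as of Il1b. That was not measured here, and the counts are not corrected for gene length, so the low ratio cannot decide. The rise was also set against Il1b alone, so less abundant members of the list were not covered. A stronger response to digestion and sorting that raises the immediate-early genes is argued against by their median. It was -0.018 (quartiles -0.212 and 0.196) against 0.65 for the cytokine list. A response that raises cytokine genes but leaves immediate-early genes level was not tested and stays open. A difference that goes with age, and a change in which macrophages passed the gate, stay open and were not tested.

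Hmox1 is a target of the oxidative stress regulator NRF2, and a wider rise of such targets is a hypothesis. The 20 other targets had a median log2 fold change of 0.29, at percentile 99.93 of 10000 matched random lists, and Gclc, Srxn1 and Txnrd1 had 0.96, 0.93 and 0.75, none past the limma threshold (adjusted p = 0.31, 0.31 and 0.478). Heme and iron handling genes stood at percentile 95.53, just past the 95th set in advance, while the iron exporter gene Slc40a1 had a log2 fold change of -1.11 (limma adjusted p = 0.224). These percentiles describe these libraries and are not tests across replicates, so both stay hypotheses.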
